A study of Tulasnella calospora and Serapias vomeracea
Tulasnella calospora with 9 samples.

How the data were processed

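RNA-seq was carried out on the orchid mycorrhizal fungus Tulasnella calospora in 3 groups of 3 libraries each: free-living mycelium fed glutamine, free-living mycelium fed ammonium, and protocorms of the orchid Serapias vomeracea colonised by the fungus, at the developmental stage the submitters call P2. Per the labels' protocols, mycelium was grown for 15 days on Modified Melin-Norkrans medium with 0.49 g of nitrogen, whereas protocorms were raised on oat agar at 20 °C in darkness. The growth medium therefore differed between the fungus in protocorms and the free-living fungus, and no group tells medium and symbiosis apart. RNA was extracted with a CTAB method and 150 bp reads were taken on an Illumina HiSeq instrument, per the labels' protocols. The labels call the libraries of a group biological replicates, and p-values measure the spread between these samples.

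Each library has a deposited count of unique gene reads and a deposited count of total gene reads for 19659 gene models of the JGI gene set Tulca1, per the file headers. The authors also deposited RPKM values. In all 9 libraries the RPKM equalled the total gene reads divided by the sum of those reads and by a whole-number gene length, which was recovered to within 0.01 nt for 18361 genes with a median of 910 nt. The aligner, its settings, the strand setting and the treatment of reads that fit several genes are not given in the sources used here, so reads of overlapping genes could not be told apart. Between 3.43% and 4.22% of the total gene reads of a library were not in the unique column. Every entry with a count has a protein ID. The sums of total gene reads ranged from 25884760 to 218953514 per library.

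Protein IDs are the only gene identity in the files, and no genome, annotation or table of gene names was used here. The gene lists that had been fixed for nitrogen uptake, carbohydrate-active enzymes, hydrophobins, proteases, conserved housekeeping genes and short secreted proteins select genes by product name or protein sequence, so none of them could be filled and no list was tested. The files do not pair protein IDs with names, and for this reason only 2 genes that rose and 2 that fell are named, by protein ID.

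Replicates were compared before they were averaged. Over 15604 genes with an expected count of at least 5, ammonium libraries 1 and 2 had a median chi-square of 0.86 per gene. Counting noise gives a median of 0.45 if every read is an independent fragment and 0.91 if a fragment is counted as 2 reads. Low counts were even more often than odd, with 5690 even and 3646 odd values between 2 and 21 unique reads over the 9 libraries. Noise was therefore judged against the value for read pairs. Each even value was set against the next higher odd value, so an even excess can arise without read pairs where higher counts are rarer. The excess thus does not settle which noise value applies, and 0.86 lies above the value for independent reads. The mean chi-square of this pair was 1.92, and the lowest among the other pairs was 42.7, for glutamine 2 and 3. Glutamine 2 and 3 were also much alike, with a median of 2.74 and a correlation of 0.997, and the next lowest mean was 216. They were kept as separate samples, and whether they are independent was not tested. Read pairs alone give a mean of 2, and the mean of ammonium 1 and 2 was 2.62 in genes with at least 10000 expected reads. The odd counts show that not every fragment was counted as 2 reads, so the true noise lies below the value for read pairs. Ammonium libraries 1 and 2 thus differed by about the sampling noise of read pairs, far less than any other pair, and were counted as 1 sample, with their reads summed. The ammonium group has n = 2 as a result, and 8 samples entered the tests. The design fixed before the data were examined had 9 libraries, and that fit is given as an alternative.

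Total gene reads were analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were kept by filterByExpr (16878 of 19659), libraries were scaled by TMM, and 1 quasi-likelihood model with the 3 groups was fitted to the 8 samples (glmQLFit, glmQLFTest). The contrasts were protocorm against the mean of both mycelia, with equal weight for each nitrogen source, protocorm against each mycelium, and glutamine against ammonium. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the size of the change divided by the square root of its F statistic. CPM values were computed from total gene reads and TMM-scaled library sizes. A gene with 0 reads in a group was compared through a floor of 3 reads over that group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

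Named genes followed a rule fixed in advance: called genes whose protocorm samples all lay above, or all below, every mycelium sample, with a mean of at least 20 CPM on the higher side, ranked by log2 fold change, with the first 2 in each direction taken. No gene met the same rule for glutamine against ammonium, since the edgeR fit to the 8 samples called none.

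The test was checked on simulated counts with the means, library sizes and dispersions of the 8 samples. For protocorm against the mean of both mycelia, 4% of 100 genes with a 4-fold change and 29% of 100 with a 16-fold change were called among 16466 genes, with 0 false calls. For glutamine against ammonium, 0% of 100 genes with a 4-fold change and 20.2% of 99 with a 16-fold change were called among 16477 genes, with 1 false call. The spread shared by the 3 groups in this fit thus leaves most changes of such sizes uncalled. It includes protocorm library 3: the common biological coefficient of variation was 1.07 with that library and 0.61 without it. Recovery for glutamine against ammonium therefore does not measure the spread of the mycelium samples alone. Unchanged genes were simulated with 1 mean over all samples. Each gene had the same dispersion in all 8 samples, so genes at 0 in protocorm library 3 alone were not simulated. Recovery and false calls therefore do not show how the test behaves with such a library.

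Alternatives covered DESeq2 1.42.0 and its size factors, upper quartile scaling, no filter, a filter of 10 CPM in 3 samples, thinning to the smallest library, 2-fold and 5-fold limits, the replicate number as a block, fits on the compared groups alone, unique gene reads, the 9 libraries kept apart, the set of mycelium libraries as a covariate, and leaving out each library. Counts of genes read in 1 state and almost absent in the other, read shares of called genes, overlaps of the most abundant genes and the comparison of nitrogen sources within sets of mycelium libraries were chosen after seeing the data, as were their values without protocorm library 3 and the simulated lists of the observed lengths. The alternatives set aside for normalized values were not needed, since the files hold counts. An exploratory edgeR fit, with several libraries left out in turn, was examined before the final analysis was settled. Figures were drawn with matplotlib 3.10.9.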

Results

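Fungal transcripts were counted in 9 libraries of Tulasnella calospora, a basidiomycete that forms mycorrhizas with orchids. Symbiotic protocorms of Serapias vomeracea, the early bodies that orchid seeds form on germination, gave 3 libraries. Free-living mycelium gave 3 libraries on glutamine and 3 on ammonium. Protocorm libraries 1, 2 and 3 held 32749857, 39660746 and 25884760 reads assigned to fungal genes. Protocorms also hold orchid tissue, and whether orchid reads were assigned to fungal gene models was not tested. The glutamine libraries held 77002255, 47060470 and 74600437 reads, and the ammonium libraries 40189365, 218953514 and 45802443. Ammonium libraries 1 and 2 differed by about the sampling noise of read pairs and were counted as 1 sample, which leaves n = 2 for that group.

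At a limit of 1 read, the fungus was read from fewer genes in protocorms than in culture. At least 1 read was found for 14760 and 14828 genes in protocorm libraries 1 and 2, against 16165 to 18006 genes in the mycelium libraries. With at least 100 reads the ranges overlapped, at 11713 and 11949 genes against 11319 to 14930. Detection in mycelium and protocorms was not compared at equal library totals. Protocorm library 3 stood apart, with reads in 7497 genes. Of the genes for which libraries 1 and 2 predicted 100 to 1000 reads, 56.8% had 0 reads in library 3, and at a predicted 1000 to 10000 reads the share was 8.56%. All 405 genes with a prediction of at least 10000 reads were detected there. Counts for protocorms are therefore also given without library 3.

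**Figure D1:**
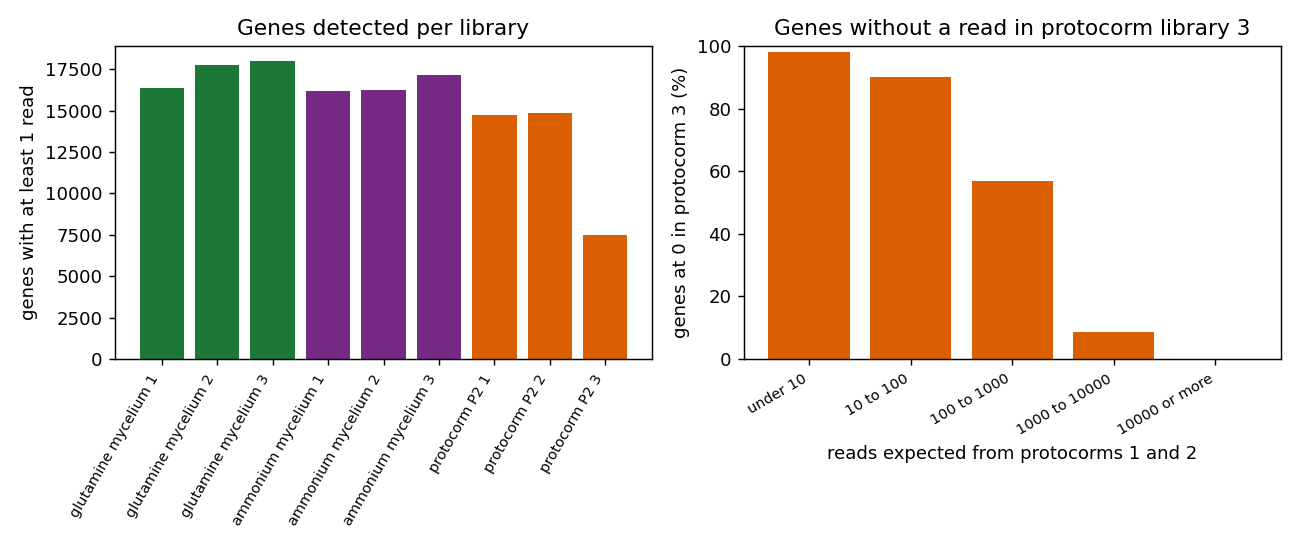
Left, the number of genes with at least 1 read (vertical axis) in each of the 9 libraries, coloured by group; right, the percentage of genes with 0 reads in protocorm library 3, by the number of reads predicted from protocorm libraries 1 and 2. Library 3 has reads in 7497 genes against 14760 and 14828 in the other protocorm libraries, and its genes without reads are mostly those predicted to be low.

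The first comparison asked which fungal genes differ between the protocorm and free-living mycelium, which also grew on another medium. Against the mean of both mycelia, 836 of 16878 genes were called, with 485 higher and 351 lower in protocorms (edgeR quasi-likelihood test, adjusted p under 0.05). Genes that rose did so by a median of 3.05 on the log2 scale, and 321 of them rose at least 5-fold. Genes that fell had a median log2 change of -2.67, and 195 fell at least 5-fold. Of the genes that fell, 123 had 0 reads over a whole group, as had 17 of those that rose, and with these genes set to the floor of 3 reads both medians and both 5-fold counts had the same values. Over all genes tested, called or not, the median log2 difference was -0.33, and it was -0.62, -0.61 and -0.14 without protocorm library 1, 2 and 3. The genes that rose took 12.4% ± 1.2 (SD, n = 3) of all reads assigned to fungal genes in protocorms, or 11.9% ± 1.33 (SD, n = 2) without library 3. The same genes took 1.72% ± 0.0263 (SD, n = 3) on glutamine and 1.79% ± 0.0141 (SD, n = 2) on ammonium. Genes that fell took 2.8% ± 0.204 (SD, n = 3) of the reads in protocorms, 9.42% ± 1.49 (SD, n = 3) on glutamine and 15.8% ± 2.6 (SD, n = 2) on ammonium. These genes were chosen on the same libraries, so the shares describe the size of the shift and are no separate evidence for it.

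The count of calls depended on the libraries. Without protocorm library 3, 3434 genes were called, 1650 higher and 1784 lower, and these included all 836 genes of the fit with 8 samples, each in the same direction. Of these calls, 510 of the 1650 higher and 1086 of the 1784 lower genes had 0 reads in library 3. That library had 0 reads in 12162 of all 19659 gene models, tested or not. In the fit with 8 samples, 135 of the 351 lower genes had 0 reads there. Leaving out glutamine library 1, 2 or 3 gave 512, 277 or 295 calls, leaving out ammonium 3 or ammonium 1 and 2 together gave 221 or 301, and leaving out protocorm 2 gave 233. The larger direction changed as well: 58% of the calls were higher in protocorms in the fit with 8 samples and 48% without protocorm library 3. DESeq2 called 3321 genes, 1322 higher and 1999 lower. With ammonium 1 and 2 kept apart edgeR called 2139, 951 higher and 1188 lower, and on libraries thinned to the smallest total 1258, 577 higher and 681 lower.

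**Figure D2:**
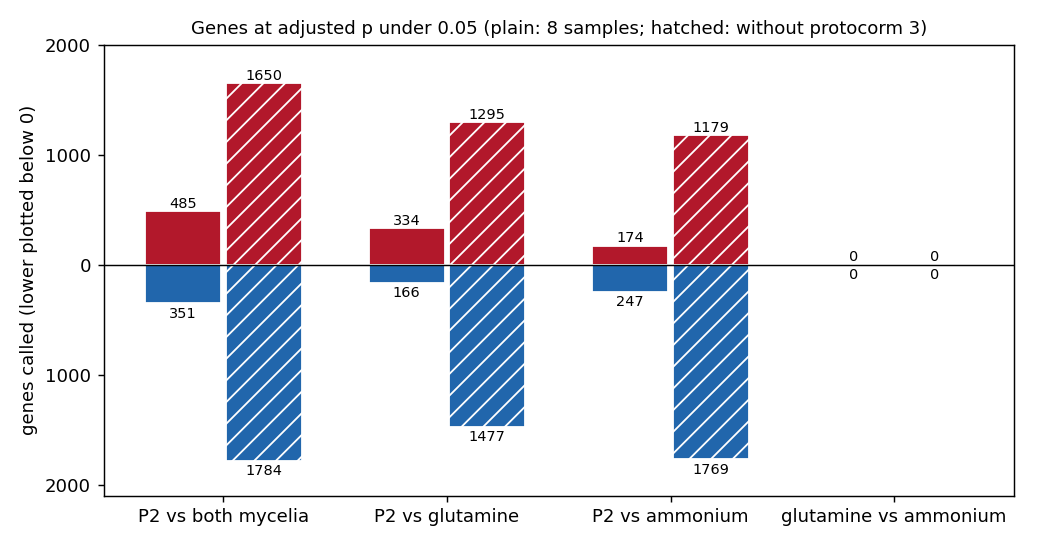
Numbers of genes at an adjusted p under 0.05 (vertical axis) for 4 comparisons, with genes higher in the first-named group above 0 (red) and genes lower in it below 0 (blue). Plain bars are the fit with 8 samples and hatched bars the fit without protocorm library 3, which raised the calls against the mean of both mycelia from 485 to 1650 higher and from 351 to 1784 lower.

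The 2 named genes that rose most were close to silent in culture. Protein ID 232903, a gene model of 494 nt, reached 248 ± 148 CPM in protocorms (SD, n = 3), against 0.0746 ± 0.108 CPM on glutamine (SD, n = 3) and 0 reads in both ammonium samples. Its pooled level was 9150 times that of mycelium, with a 95% exact counting interval of 5240 to 17700, from 12 mycelium reads in total, 10 of them in glutamine library 2. Without that library the ratio was 49000 (13500 to 404000), and without ammonium 1 and 2 it was 4740 (2710 to 9180). The fitted log2 change was 14.45 (SE 1.5, edgeR adjusted p = 0.0046), a value that depends on the prior count because ammonium had 0 reads, as do those of the other named genes. Protein ID 99078, of 624 nt, reached 144 ± 54.8 CPM in protocorms (SD, n = 3) and 0.0343 ± 0.032 CPM on glutamine (SD, n = 3), again with 0 reads on ammonium. Its pooled ratio was 9810, with an interval of 4760 to 24400 from 7 mycelium reads, 5 of them in glutamine library 3. Without that library the ratio was 28500 (7880 to 235000), and without ammonium 1 and 2 it was 5080 (2470 to 12600). Its fitted log2 change was 14.2 (SE 1.15, edgeR adjusted p = 0.002). The mycelium reads of both genes came from glutamine libraries 2 and 3 alone. Whether any protocorm reads of these 2 genes came from the orchid was not tested.

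The 2 named genes that fell most had 0 reads in all protocorm libraries. Protein ID 113773, of 1578 nt, was at 100 ± 9.8 CPM on glutamine (SD, n = 3) and 166 ± 83.5 CPM on ammonium (SD, n = 2). It was at least 4770-fold lower in protocorms, against a floor of 0.028 CPM for 3 reads over that group (fitted log2 change -16.19, SE 0.83, edgeR adjusted p = 0.00096). Protein ID 243990, of 1064 nt, averaged 1050 ± 541 CPM on ammonium (SD, n = 2) and 108 ± 176 CPM on glutamine (SD, n = 3), and was at least 20700-fold lower in protocorms (fitted log2 change -17.56, SE 3.31, edgeR adjusted p = 0.047). On glutamine it lay at 312 CPM in library 1 and at 7.07 and 5.85 CPM in libraries 2 and 3. The call of this gene in the edgeR test was lost without protocorm 1 or 2 (adjusted p = 0.07 and 0.077), without glutamine 2 or 3 (0.064 and 0.056), and without ammonium 3 or ammonium 1 and 2 together (0.13 and 0.11), and its adjusted p ranged from 0.005 to 0.13 over the alternatives. In the fit with 8 samples, 243990 was not called against either mycelium on its own (edgeR adjusted p = 0.063 for glutamine and 0.055 for ammonium). The other named genes were called against both. None of the 4 genes had reads outside the unique column.

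**Figure D3:**
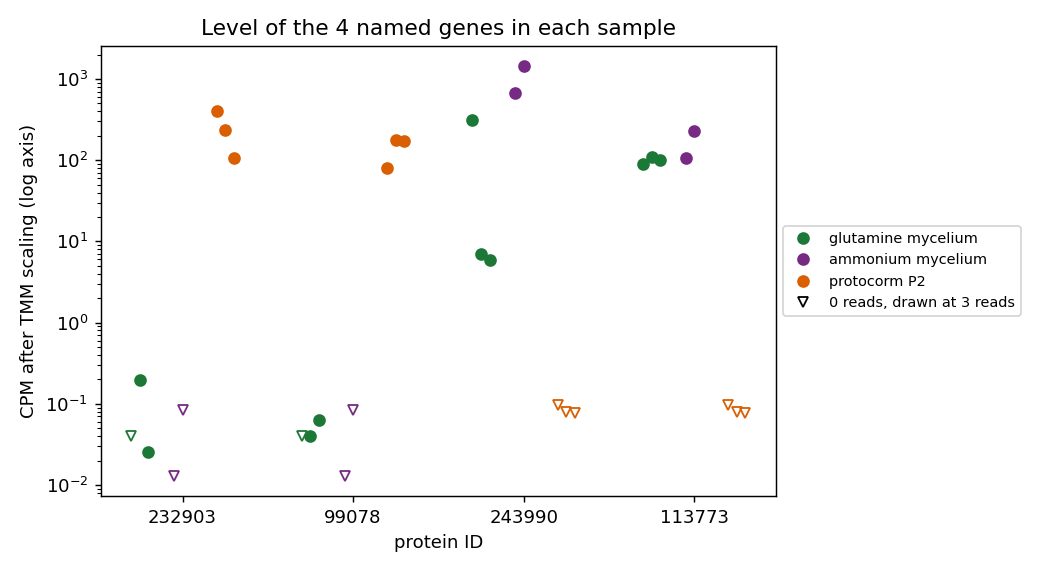
Level of the 4 named genes in CPM after TMM scaling (vertical log axis) in each of the 8 samples, by protein ID and coloured by group. Open triangles mark samples with 0 reads, drawn at the level of 3 reads. Protein IDs 232903 and 99078 are at 80.9 to 400 CPM in protocorms and under 0.2 CPM in mycelium, whereas 243990 and 113773 have 0 reads in protocorms.

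Genes read in one state and almost absent in the other were then counted. In 119 genes every mycelium sample had at least 1 CPM and every protocorm library had 3 reads or fewer, and 7 of them had a mean of at least 20 CPM in mycelium. With library 3 left out the number was 123. Conversely, 16 genes had at least 1 CPM in protocorm libraries 1 and 2 and 3 reads or fewer in every mycelium sample, and with library 3 required as well there were 3, which are not named because the files do not pair IDs with names. The limit of 3 reads stands for 0.013 CPM in the summed ammonium 1 and 2, but for 0.078 to 0.096 CPM in the protocorm libraries. Absence was therefore harder to reach across the mycelium samples, and the numbers of the 2 directions cannot be compared. Across the 16878 genes tested, the protocorm samples lay above all mycelium samples in 6.88% and below all of them in 17.8%. Chance gives 1.79% in each direction. Library 3 has 0 reads in 12162 genes, which places genes below and keeps them from lying above. Without it the shares were 16.5% above and 21.4% below, where chance gives 4.76%.

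The most abundant transcripts of protocorms overlapped with those of both mycelia. Of the 100 genes with the highest mean CPM in protocorms, 64 were among the top 100 on glutamine and 33 among the top 100 on ammonium. The mycelia shared 48, and lists drawn at random would share 0.51. These overlaps were not tested against each other. Of the top 100 genes of protocorms, 14 were called higher than in mycelium. Of the 152 genes in either mycelium's top 100, 34 were called lower in protocorms. Without library 3 the overlaps of protocorms were 65 with glutamine and 31 with ammonium, 28 of their top 100 genes were called higher, and 41 of the 152 mycelium genes were called lower.

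Each nitrogen source was also compared with the protocorm on its own. Against glutamine mycelium 500 genes were called, 334 higher and 166 lower in protocorms. Against ammonium mycelium 421 genes were called, 174 higher and 247 lower (edgeR, adjusted p under 0.05). The share of called genes that were higher was thus 66.8% against glutamine and 41.3% against ammonium, a difference that was not tested. The gap was small or turned round in 4 fits, where these shares were 38.5% and 39.3% with DESeq2, 39.1% and 34.3% with ammonium 1 and 2 kept apart, 39.2% and 42.7% on the compared groups alone, and 46.7% and 40% without protocorm library 3. In the other alternatives the share was higher against glutamine each time, at 62.3% to 78.8% against 28.6% to 62.5%. In both comparisons 155 genes were higher and 100 were lower. Independent lists of these sizes would share 3.4 and 2.4 genes. In 20 simulations of unchanged groups with shared protocorm libraries no gene was called, so lists as long as the observed ones were taken there by smallest p. These shared a mean of 20.2 higher genes (13 to 30) and 70.8 lower genes (61 to 84). The simulations did not copy the genes at 0 in protocorm library 3 alone, so these overlaps may differ from those of unchanged groups with such a library. Part of the overlap may come from the shared protocorm libraries, which are too few to split. Without protocorm library 3 the counts were 2772 against glutamine, 2948 against ammonium and 1764 in both. DESeq2 gave 2789, 2775 and 1835, edgeR with ammonium 1 and 2 kept apart 1672, 1948 and 1269, and edgeR on the compared groups alone 932, 117 and 72. Other libraries moved these counts as well. Against glutamine they were 284, 72 and 62 without glutamine 1, 2 and 3, 289 and 85 without protocorm 1 and 2, and 293 and 304 without ammonium 3 and without ammonium 1 and 2. Against ammonium they were 112 and 96 without glutamine 2 and 3, 103 and 16 without protocorm 1 and 2, and 7 and 89 without ammonium 3 and without ammonium 1 and 2. The number of genes called in both was 150, 55 and 49 without glutamine 1, 2 and 3, 95 and 16 without protocorm 1 and 2, and 7 and 50 without ammonium 3 and without ammonium 1 and 2.

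The last comparison asked how the nitrogen source altered free-living mycelium. The edgeR test called 0 of 16878 genes between glutamine and ammonium, and the smallest adjusted p was 0.41. At an unadjusted p under 0.05 there were 1355 genes, 423 higher and 932 lower on glutamine, where 844 would be expected by chance. This count varied with the samples in the edgeR fit. It was 3758 of 16917 genes without protocorm library 3 and 4725 of 16950 with mycelium alone. Without glutamine 2 or 3 it was 609 of 16672 or 628 of 16700. Leaving out glutamine 1, protocorm 1 or protocorm 2 gave 1436, 1361 or 1236. DESeq2 called 359 genes, 65 higher and 294 lower on glutamine, and edgeR without glutamine library 1 called 71 genes, all lower on glutamine. The glutamine samples lay entirely above the ammonium samples in 28.5% of genes and entirely below in 24.5%, against 10% by chance in each direction. That chance value takes the samples as interchangeable, whereas glutamine 2 and 3 correlated at 0.997. Over 10527 genes without TMM scaling, the split by nitrogen source separated 63.7% and the split of glutamine 2 and 3 against the rest 64.2%. The excess over chance therefore cannot be credited to the nitrogen source.

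The mycelium libraries fell into sets by the number of genes with a read. Glutamine 1 and ammonium 1 and 2 had reads in 16165 to 16365 genes, and glutamine 2 and 3 and ammonium 3 in 17130 to 18006. These sets were defined from the data, after the results had been seen, and each holds samples of both nitrogen sources, too few to test within a set. The nitrogen difference was computed within each set for 10527 genes with a mean of at least 5 CPM in mycelium. Across these genes, which are not independent replicates, the log2 differences of the sets had a Pearson correlation of 0.67. Differences of over 2-fold in both sets were higher on glutamine in 469 genes, lower in 137, and opposite in 3. With the ammonium samples exchanged between the sets the correlation was 0.59, with 1197 genes higher, 495 lower and 26 opposite. These differences used plain library totals, without the TMM factors of 1.009 to 1.084 for glutamine and 0.881 and 0.755 for ammonium samples. Leaving the factors out shifts every difference toward glutamine, so the excess of higher genes says nothing on direction. In the TMM-scaled edgeR test, 423 genes were higher and 932 lower on glutamine at an unadjusted p under 0.05. In a fit of mycelium alone edgeR again called 0 of 16950 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 4725. With the set as a covariate these numbers were 0 and 5219.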

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

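Summing ammonium 1 and 2 was decided from the data, so the fit that keeps them apart follows the first design and became an alternative afterwards. Unique gene reads, ammonium 1 and 2 left out together and the library set as covariate were chosen after seeing the data; the other alternatives were fixed before the data were examined. The 5 counts of calls (protocorm against the mean of both mycelia, glutamine, ammonium and both separately, and glutamine against ammonium) stayed within 1.5 times their values under DESeq2 size factors, upper quartile scaling, no filter, the stricter filter, unique gene reads and the 2-fold limit. DESeq2 gave 3321, 2789, 2775, 1835 and 359 calls in that order. With ammonium 1 and 2 kept apart as separate samples, the 4 protocorm counts were 2139, 1672, 1948 and 1269. Fits on the compared groups alone gave 932 against glutamine, 117 against ammonium and 72 in both. For the mean of both mycelia, thinning gave 1258 and the 5-fold limit 516. The causes of these moves were not tested, except that the 5-fold limit leaves out smaller changes by construction and that summing ammonium 1 and 2 removes a residual degree of freedom. Leaving out single libraries gave 221 to 3434 calls for the mean of both mycelia, 62 to 2772 against glutamine, 7 to 2948 against ammonium, 7 to 1764 in both and 0 to 71 for glutamine against ammonium; where ammonium was left with 1 sample, that sample was assumed to vary like the other groups. Upper quartile scaling moved the median log2 difference of all genes from 0.06 to 0.21 between glutamine and ammonium and from -0.32 to -0.17 between protocorm and ammonium, and DESeq2 size factors moved it from -0.35 to -0.45 between protocorm and glutamine. DESeq2 gave -0.12 between glutamine and ammonium over 5180 genes, the opposite sign, and -0.47 between protocorm and glutamine. For the mean of both mycelia this median was -0.33, and -0.16 with the stricter filter and -0.67 with the replicate block.

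The replicate numbers are shared by the groups, but same-numbered libraries did not deviate together: correlations ran from -0.21 to 0.22 and exceeded 0.1 in 1 of 9 pairs, and 3 of 9 libraries correlated best with their own number. With the number as a block, in a fit that kept ammonium 1 and 2 apart, 580 genes were called against the mean of both mycelia, 276 against glutamine, 399 against ammonium, 202 in both and 0 between glutamine and ammonium. Of the 4 named genes, 232903, 99078 and 113773 kept their direction and their call under every alternative run. The call of 243990 was lost with the block (adjusted p = 0.059) and under 6 of the fits that left out libraries (adjusted p = 0.056 to 0.13), its direction was kept in every edgeR fit, and DESeq2 gave it no adjusted p. Alternatives for the fixed gene lists were not run because no list could be filled. The common biological coefficient of variation was 1.07 over the 8 samples and 0.61 without protocorm library 3. Depth was varied by thinning alone.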

Other observations

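The tests of gene length, successive protein IDs, protocorm library 3, ammonium libraries 1 and 2 and the order of the mycelium samples were chosen after the results were seen; the counts of calls under other splits of the samples were not.

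Genes called higher in protocorms had slightly shorter gene models than random lists matched on mean expression over the 8 samples. That matching does not equal the level in protocorms or in mycelium. The called genes had a median length of 1137 nt, just below the central 95% of 10000 such lists (1147 to 1287 nt). A hypothesis that longer models were favoured in this set is not borne out by this median; its criteria had not covered a value below the range, and this reading was settled after the result was seen. Genes called lower had a median of 1178 nt, just above the range of their own matched lists (1005 to 1175 nt).

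The 119 genes read in every mycelium sample and almost absent from protocorms were tested for the hypothesis that stretches of the genome were missing, under the untested assumption that protein IDs follow gene order. They held 1 pair of successive IDs, while random lists from the 11965 genes read in all mycelia held a median of 0 and a 95th percentile of 1, so the test decides nothing.

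The number of calls between protocorm and mycelium was set against other splits of the samples. In a fit with 2 groups the real split of 3 against 5 samples called 1340 genes, and 1 of the 56 splits, the real one, reached that number. The highest of the others was 42. A share of 1 in 56 is the smallest these splits can give, so chance is unlikely for this count but not excluded. The 836 calls of the fit with 3 groups were not tested in this way. For protocorm against glutamine the real split called 932 genes and the highest other 0, with 1 of 10 splits reaching the real value, and 10 splits are too few for a share under 0.05.

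Protocorm library 3 had reads in 7497 genes, against 14760 and 14828 in the other protocorm libraries. Its smaller total is argued against as the cause, because libraries 1 and 2 thinned to that total still had reads in 1.97 times as many genes or more. A fixed read limit below which values were set to 0 is argued against by 330 genes with 1 to 99 reads. Few starting fungal molecules, each amplified to many reads, remain a candidate explanation: among genes predicted to have 10 to 100 reads, 3461 of 3844 were at 0, and those not at 0 had a median of 11.75 times their prediction, while at a prediction of 1000 to 10000 the ratio was 1.08. No biological explanation was tested, since the labels give the 3 libraries 1 group.

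Ammonium libraries 1 and 2, of 40189365 and 218953514 reads, may be 1 library sequenced at 2 depths, which cannot be told apart from separate libraries of 1 sample. Their median chi-square per gene was 0.86, where read pairs counted as 2 reads give 0.91, and their correlation was 0.999. Odd counts place the true noise below 0.91, and the mean chi-square was 2.62 in genes with at least 10000 expected reads, where read pairs give 2. The labels call them biological replicates, and the files alone do not say how the libraries were made.

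The 5 mycelium samples were compared along the difference between ammonium and glutamine. The values of this comparison used plain library totals, without TMM scaling. On an axis from the mean of ammonium (0) to the mean of glutamine 2 and 3 (1), ammonium 3 was at -0.24, ammonium 1 and 2 at 0.24 and glutamine 1 at 0.58. The ammonium samples lie evenly around 0, and glutamine 2 and 3 average 1, by construction. Only glutamine 1 did not enter the axis. Swapped labels of glutamine 1 and ammonium 3 are argued against, because ammonium 3 correlated better with ammonium 1 and 2 than with glutamine 2 or 3, by 0.208. Whether glutamine 1 alone carries a wrong label cannot be told apart from a weaker response, since 0.58 lies between the ammonium range and the other glutamine libraries. Over the 10527 genes glutamine 1 correlated better with ammonium 1 and 2 (0.959) than with glutamine 2 (0.924). Over all genes it correlated at 0.97 and 0.971 with glutamine 2 and 3, at 0.973 with ammonium 1 and with ammonium 2, and at 0.931 with ammonium 3. Ammonium 1 and 2 also share its set by the number of genes with a read. The correlations therefore do not decide on the label. The nitrogen source stays open as well: 6704 of 10527 genes separated the real groups without overlap, but the split of glutamine 2 and 3 against the rest separated 6759, so that 2 of the 10 splits reached the real value.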
